A study of Caulobacter vibrioides NA1000 with 15 samples.

How the data were processed

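RNA of Caulobacter vibrioides NA1000, a freshwater alphaproteobacterium, was measured on 15 Agilent arrays of 2 colours, in 5 groups of 3 arrays. On 12 arrays, 3 for each mutant, RNA of a deletion mutant (phyK, phyR, sigT or sigU) carried Cy5 and RNA of the wild type carried Cy3, both from cells in exponential growth in glucose minimal medium that had spent 30 min with 150 mM of added sucrose. On the other 3 arrays, RNA of a sigT mutant overexpressing sigU carried Cy5 and RNA of the sigT sigU double mutant carried Cy3, without treatment. Per the labels, all arrays had the same dye orientation, so a gene-specific dye effect stays in every ratio against 0 and cancels in differences between mutants. The series' design text calls all samples biologically independent, and p-values here measure the spread between arrays. The labels do not say whether wild type extracts were shared between arrays.

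The deposited scanner files hold spot intensity values for each channel on a linear scale, with median local background, and come from Agilent Feature Extraction, version 9.0 per the submitters' processing notes and 9.5.3.1 per the file headers. The same deposited files hold processed intensity values, which the software subtracted for background and normalized between dyes, per the file headers. The log10 ratio of Cy5 over Cy3 in the deposited files was computed by the software from these processed values. The authors' deposited value table holds log10 ratios, Cy5 over Cy3, as settled by setting each column against the scanner files. Its slope on the scanner ratio was 1 on each array, and the largest difference was 0.005 on sigU overexpression replicate 1 and 0.0005 on the others. Column medians of that table lay between -0.02 and 0.008, and 0 of its columns were left unused. Scale, direction and lack of further centring of the table are thereby known. The genome build of the probe design is not given in the sources used here.

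The arrays tile the start of genes. Each held 43979 probes outside the controls, 39307 sense and 4396 antisense to a locus, and 276 over the replication origin region. Probes had 60 bases and a median step of 51 bases, and the start codon lies 400 bases into the tiled window of a locus. Of 3710 loci with that position covered, 3710 had ATG, GTG or TTG there. A gene's value was the median log2 ratio of its sense probes that begin in the coding sequence, 1 to 3 per gene with a median of 3, for 3751 genes. The design fixed earlier speaks only of the probes of a gene and leaves out intergenic ones. The restriction to coding probes was set after the probe layout had been seen and before any comparison was fitted. Probes along the window of 1 locus measure different parts of the transcript and are described separately where named. Of the genes, 24 share a coding probe sequence with another locus.

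Median signals before background correction were 321 to 861 in Cy3 and 227 to 724 in Cy5, against median backgrounds of 43 to 50 and 43 to 49. Between 91.6% and 98.9% of probes were well above background in Cy3 and between 88.6% and 98.8% in Cy5. Lower genes without Cy5 signal above background on any array, and higher genes without such Cy3 signal, numbered 0. For 1 gene called in the sigT mutant this signal was above background on only 1 or 2 arrays in its best probe. Called genes with a saturated spot numbered 9, 8, 10, 1 and 0 in the phyK, phyR, sigT and sigU mutants and with overexpression, and 0 had all probes saturated on all arrays. Saturated spots stay in the gene values. Spots flagged as outliers numbered 388 to 2343 on the mutant arrays and 2915 to 4348 on the overexpression arrays.

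Background was corrected with limma's normexp (offset 50), and log2 ratios were normalized within each array by loess, with control and outlier spots at weight 0 and left out afterwards. All 15 arrays entered 1 group-means model in limma with 10 residual degrees of freedom. A gene was called when the limma p, adjusted by Benjamini-Hochberg over all genes, was under 0.05 and the ratio was at least 2-fold. Differences between mutants were contrasts of the same model. Overlaps are given with the number that independent lists of the same sizes would share, and with the mean over 20 simulated sets of unchanged groups sharing wild type RNA. Gene lists were tested with camera at a preset correlation of 0.01, with an estimated correlation beside it and with fry as an alternative. The median log2 ratio of all genes was tabulated in the 5 groups for the settings that refit all arrays. It was lowest with median centring in the sigU mutant, at -0.0764, and highest with the deposited table and sigU overexpression, at 0.0836. Versions were R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

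Design, alternatives, gene lists and the rule for named genes were fixed before the data were examined. That rule takes phyK, phyR, nepR, sigT and sigU in each comparison, the up to 10 called genes with the lowest and with the highest ratio among those with the same sign on all 3 arrays, up to 4 members of each list, up to 5 genes each way per contrast and up to 10 per overlap. The files identify genes by locus tag without names. Of the tags, 0 matched a row of the RefSeq table given (assembly ASM2200v1), which lists other tags. Symbols are printed only for members of the lists fixed by tag, as published locus assignments, not as annotation in the files. Of the other genes the rule takes, only 2 that fell and 2 that rose are printed, by their tags, and the remainder enters as counts. These were taken by the mean over the phyK, phyR and sigT mutants, a choice made after the first fit. Of 16 lists fixed, 3 were given by tag and were tested: general stress regulators, cell cycle regulators and xylose catabolism. The other 13 were defined by words of the gene product and were not analysed here.

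The pipeline was tested on simulated data for the sigT mutant comparison with 3751 genes, of which 200 were changed. All 100 genes changed 3-fold and all 100 genes changed 5-fold were called, along with 0 unchanged genes. No gene was called in the 4 unchanged groups, a count of 0.

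Replicate numbers were checked for pairing through the correlation of deviations from the group means. Any pairing read this way comes from these data, not from the labels. Same-numbered arrays correlated at 0.236 to 0.663 between phyK and phyR mutants and at 0.101 to 0.29 between phyK and sigT mutants. They did so at 0.121 to 0.198 between phyK and sigU mutants and at 0.213 to 0.292 between phyR and sigU mutants. Numbers may thus pair these. Slide may contribute, since phyK replicate 2 and phyR replicate 1, of other number but on 1 slide, had 0.387. The lowest correlation was 0.0618 between phyR and sigT mutants, whose replicates 2 and 3 had 0.327 and 0.328. It was 0.0263 between sigT and sigU mutants, and pairing of these groups is not settled. No same-numbered pair with the overexpression arrays exceeded 0.0873, so those share only a number. Slides partly follow the numbers. Slide 1 held phyK replicates 1 and 2, phyR replicate 1 and sigU replicate 1. Slide 2 held replicate 3 of all 4 mutants. Slide 3 held phyR replicate 2, sigT replicates 1 and 2 and sigU replicate 2. Slide 4 held overexpression replicates 2 and 3, and the slide of replicate 1 is not known.

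Alternatives were other background corrections, normalizations, filters, probe summaries, sample sets, prior settings, array weights, replicate and slide blocks, the deposited table, no fold minimum, left-out arrays and other list tests. Alternatives chosen after seeing the data were all sense probes, coding probes with those spanning the start codon, only genes with values on all 3 arrays, leaving out loci that share probes, removing a trend with probe G content, and leaving out of lists and overlaps the genes that the strains delete or overexpress.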

Results

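Transcript levels of Caulobacter vibrioides NA1000 were compared on 15 arrays between 4 deletion mutants and the wild type under sucrose stress, and between a sigT mutant overexpressing sigU and a sigT sigU double mutant without stress. PhyK is a sensor kinase, PhyR a response regulator that binds the anti-sigma factor NepR, and SigT and SigU are sigma factors of the extracytoplasmic function family. The title of the series names the genes that depend on each of these proteins. Each comparison had 3 arrays, and negative log2 ratios mean less RNA in the Cy5 sample, the mutant or the overexpressing strain. Errors are SD over 3 arrays unless stated. Correlations across genes between arrays of 1 group were 0.823 to 0.919 for the phyK, phyR and sigT mutants, 0.591 to 0.803 for the sigU mutant and 0.648 to 0.732 for the overexpression arrays.

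The targeted genes were read first. The sigT transcript had a log2 ratio of -3.60 ± 0.26 (SD, n = 3) in the sigT mutant, phyR had -2.74 ± 0.02 (SD, n = 3) in the phyR mutant, phyK had -1.09 ± 0.27 (SD, n = 3) in the phyK mutant and sigU had -2.38 ± 0.83 (SD, n = 3) in the sigU mutant. On sigU mutant replicate 3 the sigU value was -1.42, against -2.95 and -2.76 on the others. In the overexpressing strain sigU rose to 5.08 ± 0.12 (SD, n = 3). These probes lie within the first part of each gene, and where they lie outside the deleted part they check nothing. The values in the 4 mutants also do not separate deletion from lost expression. In the sigT mutant phyR had -2.61 ± 0.23, phyK -1.15 ± 0.07 and sigU -3.33 ± 0.28 (SD, n = 3). The sigT transcript itself had -2.90 ± 0.08 in the phyK mutant and -2.95 ± 0.12 in the phyR mutant (SD, n = 3).

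**Figure D1:**
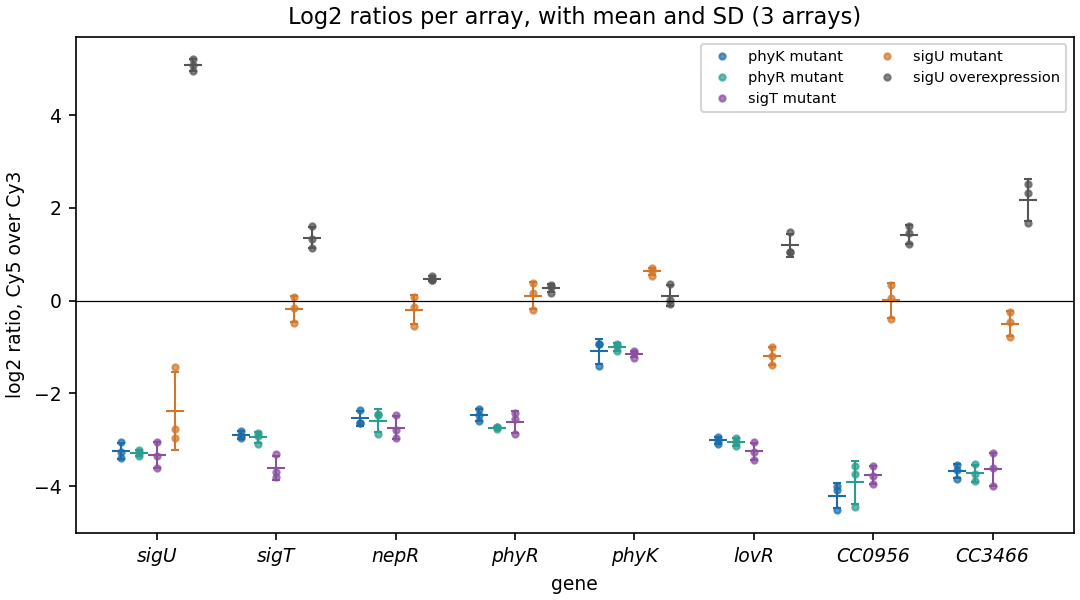
Log2 ratios, Cy5 over Cy3, of 8 genes on each array (points), with mean (dash) and SD (bars) over 3 arrays, in the 5 groups. The sigU value is 5.08 with sigU overexpression and -3.24 to -3.33 in the phyK, phyR and sigT mutants.

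Loss of phyK lowered the regulators of the stress response itself. The sigU transcript fell to -3.24 ± 0.17, sigT to -2.90 ± 0.08, nepR to -2.54 ± 0.16, phyR to -2.47 ± 0.13 and lovR, the response regulator gene of the LovK photoreceptor kinase, to -3.01 ± 0.08 (SD, n = 3). Among all genes 78 were lower and 96 higher. Among the lowest were CC0956 at -4.20 ± 0.28 and CC3466 at -3.68 ± 0.15, and among the highest were CC2696 at 3.02 ± 0.41 and CC2740 at 2.64 ± 0.63 (SD, n = 3). In CC3466, 1 of 2 probes was saturated in wild type RNA on 2 arrays, and the other had -3.86 ± 0.05 (SD, n = 3). For CC0956 the limma adjusted p was 2.91e-11. Of 8 general stress regulators 6 were lower, with a median of -2.51 (limma camera adjusted p = 3.3e-05, and adjusted p = 0.0428 with an estimated correlation). Without the deleted gene phyK itself these were 0.000212 and, with an estimated correlation, 0.0527. Adjusted over the list alone, 6 were also lower. The remaining 2 were lovK, at 0.27 ± 0.10, and the response regulator gene mrrA, at 0.14 ± 0.04 (SD, n = 3). The list was chosen from published knowledge of this pathway. With slide as a fixed block, 74 genes were lower and 95 higher. On slide 1 all 78 lowered genes had the same direction, and on slide 2 it was 77, all that had a value there. All 96 raised genes kept their direction on both slides. Since these genes were called on the same arrays, agreement in direction was close to fixed beforehand, here and in the slide readings below.

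The phyR mutant was compared with the wild type to find genes that depend on the response regulator. The sigU transcript fell to -3.28 ± 0.06, sigT to -2.95 ± 0.12, nepR to -2.59 ± 0.25 and lovR to -3.05 ± 0.08 (SD, n = 3), while phyK was 1.99-fold lower and missed the fold minimum. Counts were 72 lower and 106 higher. CC0956 had -3.92 ± 0.47 and CC3466 -3.72 ± 0.18, while CC2696 had 2.94 ± 0.38 and CC2740 2.90 ± 0.38 (SD, n = 3). The saturated probe of CC3466 was so on 2 arrays here, and the other had -3.91 ± 0.15 (SD, n = 3). The limma adjusted p of sigU was 4.08e-09. General stress regulators had 5 of 8 lower, also 5 when adjusted over the list alone, with a median of -2.66 (limma camera adjusted p = 6.2e-05). That call was lost with an estimated correlation (adjusted p = 0.0502). Without phyR itself the limma camera adjusted p was 0.000945, and 0.0703 with an estimated correlation. With slide as a fixed block the counts were again 72 and 106, and on slides 1, 3 and 2 the lowered genes kept their direction in 72, 72 and 71 cases, the last being all with a value there. All 106 raised genes kept theirs on each of these slides. Both sets were called on these same arrays, so their direction decides little.

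Deletion of sigT asked which genes need this sigma factor. The sigU transcript fell to -3.33 ± 0.28, nepR to -2.74 ± 0.25, phyR to -2.61 ± 0.23, lovR to -3.25 ± 0.19 and phyK to -1.15 ± 0.07 (SD, n = 3). Counts were 74 lower and 120 higher. CC0956 had -3.76 ± 0.20 and CC3466 -3.63 ± 0.35, and CC2696 had 3.45 ± 0.09 and CC2740 3.03 ± 0.23 (SD, n = 3). That probe of CC3466 was saturated on all 3 arrays, and the other had -4.09 ± 0.29 (SD, n = 3). For lovR the limma adjusted p was 2.13e-12. Of 8 general stress regulators 6 were lower (6 adjusted over the list alone), with a median of -2.68 (limma camera adjusted p = 2.42e-05, and adjusted p = 0.0396 with an estimated correlation). Without sigT itself these were 0.000454 and, with an estimated correlation, 0.0425. The DNA methyltransferase gene ccrM was higher, at 1.15 ± 0.20 (SD, n = 3). With slide as a fixed block, 71 genes were lower and 113 higher. On slide 3 all 74 lowered genes kept their direction, and on slide 2 it was 73. Of 120 raised genes 119 and 120 did. Those missing, 1 lowered and 1 raised gene, had no value there. As before, the genes were picked on these arrays, so kept directions are no independent check.

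**Figure D2:**
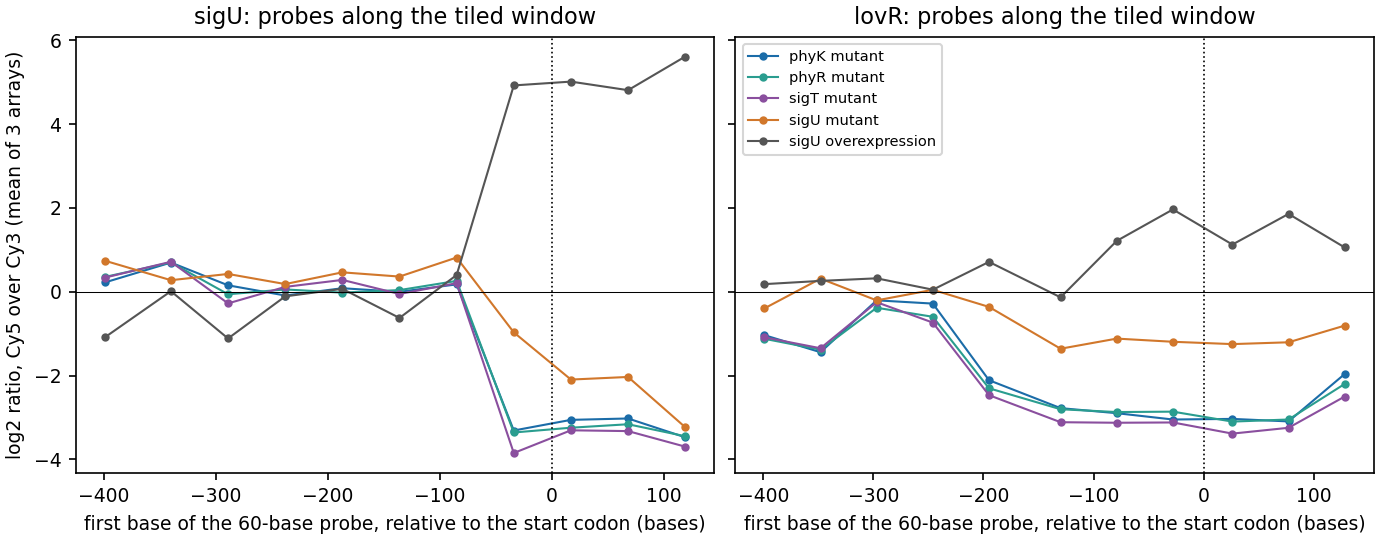
Log2 ratio, Cy5 over Cy3, of each sense probe along the tiled window of sigU (left) and lovR (right), against the probe's first base relative to the start codon (dotted line), as the mean of 3 arrays in the 5 groups. For sigU in the sigT mutant the value is 0.21 at base -85 and -3.85 at base -34.

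Probes along the windows showed where the ratio changed. In sigU the probe beginning at base -85 had 0.18, 0.26 and 0.21 in the phyK, phyR and sigT mutants, and the probe beginning at base -34 had -3.31, -3.36 and -3.85. With overexpression these probes had 0.40 and 4.92. In lovR the probes beginning at bases -399, -348, -297 and -246 had -1.09, -1.35, -0.25 and -0.74 in the sigT mutant, and the next, at base -195, had -2.47. These are means of 3 arrays without a test of position.

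The phyK, phyR and sigT mutants shared most of their changed genes. Of 88 genes lower in any of the 3 mutants, 62 were lower in all, where independent lists would share 0.0295. Of 138 genes higher in any, 83 were higher in all, where independent lists would share 0.0868. Without the deleted genes phyK, phyR and sigT, 60 were lower in all, against 0.0265. The 62 included sigU, sigT, nepR, phyR, lovR, CC0956 and CC3466. Unchanged groups with shared wild type RNA gave 0 such genes in 20 simulated sets, and neither number accounts for real effects and shared RNA together. Ratios correlated across genes at 0.974 between phyK and phyR mutants, 0.95 between phyK and sigT mutants and 0.961 between phyR and sigT mutants, against simulated values of 0.501, 0.511 and 0.497. The covariances were 0.228, 0.228 and 0.24, against simulated covariances of 0.00524, 0.00535 and 0.00519. The simulated correlations follow from the simulation, where shared and unshared parts have equal spread, and are no yardstick. Genes are not independent replicates.

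**Figure D3:**
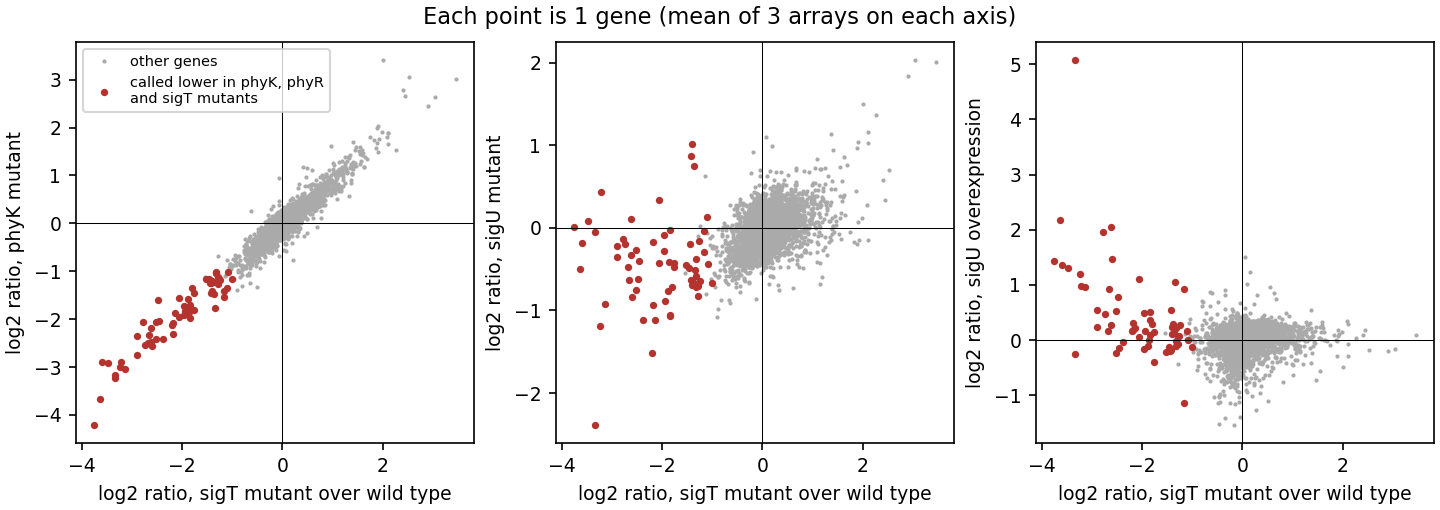
Mean log2 ratio of each gene (3 arrays per axis) in the sigT mutant, on the horizontal axes, against the phyK mutant, the sigU mutant and sigU overexpression, on the vertical axes. Red points are the 62 genes lower in the phyK, phyR and sigT mutants. Their medians are -1.82, -0.44 and 0.22 on the vertical axes.

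Direct contrasts between these mutants found no gene past the call. Between phyR and phyK mutants limma called 0 of 3747 genes, with 74 at an unadjusted p under 0.05. Between sigT and phyK mutants it called 0 of 3748, with 256, and between sigT and phyR mutants 0 of 3750, with 142. Without any difference, a share of about 0.05 of the genes would have such a p. The sigT transcript differed by -0.71 (SE 0.15) between sigT and phyK mutants (limma adjusted p = 0.495) and by -0.66 (SE 0.15) between sigT and phyR mutants (limma adjusted p = 0.311). The differences in sigU were -0.05, -0.10 and -0.05, and those in lovR -0.04, -0.24 and -0.20. General stress regulators were lower in the sigT mutant than in the phyK mutant by limma camera (adjusted p = 0.00853, but adjusted p = 0.217 with an estimated correlation) and than in the phyR mutant (adjusted p = 0.0293, but adjusted p = 0.204 with an estimated correlation), with 0 of 8 members called in both. Without the deleted genes the limma camera adjusted p was 0.22 and 0.108, and 0.46 and 0.204 with an estimated correlation, while the list medians were -0.12 and -0.12 both with and without them. With slide as a fixed block the 3 counts stayed at 0. Within single slides the SD of the differences over genes was 0.156 and 0.158 for the phyR and phyK mutants, 0.162 for the sigT and phyK mutants and 0.181 and 0.225 for the sigT and phyR mutants.

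Loss of sigU changed fewer genes. The lovR transcript fell to -1.19 ± 0.19 (SD, n = 3), sigU to -2.38, and 8 genes in all were lower and 11 higher. CC2696 rose, with 3.03, 2.90 and 0.08 on the 3 arrays, and CC2740 rose to 2.03 ± 1.57 (SD, n = 3), with 0.23 on replicate 3. The sigT, nepR and phyR transcripts had -0.18 ± 0.28, -0.20 ± 0.31 and 0.11 ± 0.29, and CC0956 had 0.01 ± 0.37 (SD, n = 3), all without a call. For lovR the limma adjusted p was 2.51e-06. All 8 lowered genes were also lower in the phyK and phyR mutants, and 7 were lower in the sigT mutant, where independent lists would share 0.158. Without sigT and sigU themselves 6 were lower in both, against 0.134. Across genes the ratios correlated with those of the phyK, phyR and sigT mutants at 0.554, 0.514 and 0.5. Simulated unchanged groups with shared wild type RNA gave 0.494, 0.502 and 0.494. That level follows from the simulation, where shared and unshared parts have equal spread, so comparing correlations decides nothing. The covariances were 0.0661, 0.0639 and 0.0639, against simulated covariances of 0.00515, 0.00522 and 0.00515. Shared RNA alone thus gave far smaller covariances in the simulation than these groups had. A wild type extract common to all arrays was not simulated. Of the 62 genes lower in the phyK, phyR and sigT mutants, 53 had ratios below 0, with a median of -0.44. Of 8 general stress regulators 2 were lower (2 adjusted over the list alone), and the list as a whole had a limma camera adjusted p of 0.939. Its median was -0.03 and its mean -0.33, while the test's direction was up. Other scalings gave 16 lower and 21 higher genes (the software's processed signals), 17 and 20 (median centring) and 16 and 19 (deposited table). Leaving out sigU mutant replicate 3 gave 17 lower genes, and leaving out replicate 2 gave 5. With slide as a fixed block the counts were 8 and 11. The 8 lowered genes kept their direction on slides 1, 3 and 2. The 11 raised genes did in 11, 11 and 10 cases, with a median of 1.85, 1.78 and 0.23. Picked on these arrays, such genes are nearly bound to keep their direction.

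A direct contrast tested sigU against sigT loss. The ratio was higher in the sigU mutant than in the sigT mutant by 3.42 (SE 0.15) for sigT, 2.72 (SE 0.13) for phyR, 2.54 (SE 0.16) for nepR, 2.06 (SE 0.13) for lovR and 3.76 (SE 0.22) for CC0956. It was lower by 1.57 for ccrM, at -1.57 (SE 0.16). In total 132 genes differed, 83 lower and 49 higher in the sigU mutant. For sigT the limma adjusted p was 3.04e-09. General stress regulators had 5 of 8 members higher, 5 adjusted over the list alone (limma camera adjusted p = 4.48e-10, and adjusted p = 0.00453 with an estimated correlation). Without sigT and sigU these were 1.53e-07 and, with an estimated correlation, 0.00709. With slide as a fixed block 129 genes differed. Within slides 2 and 3, 131 and 132 of the 132 had the same direction, 131 being all with a value on slide 2. The 132 were called on arrays that include these, so this restates the calls.

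Overexpression of sigU in cells without sigT raised genes of the sigT-dependent set. Besides sigU itself, CC3466 rose to 2.17 ± 0.44, CC0956 to 1.43 ± 0.20, lovR to 1.19 ± 0.25 and the sigT probes to 1.36 ± 0.23 (SD, n = 3). Both strains lack sigT, and its 2 coding probes had 0.02 and 2.69. The phyR, nepR and phyK transcripts had 0.27 ± 0.08, 0.47 ± 0.05 and 0.11 ± 0.23 (SD, n = 3), without a call. In total 16 genes were lower and 14 higher, 53.3% lower, against 20 and 27, 42.6% lower, with the software's processed signals. For lovR the limma adjusted p was 6.43e-07. Of the 14 higher genes 11 were among the 62 lowered in the phyK, phyR and sigT mutants, and independent lists of the sigT mutant and of overexpression would share 0.276. These 11 include sigU, which is overexpressed, and sigT, which both strains lack, and 9 remain without them, against 0.23. Why the sigT value rose was not tested. Of the 62, 45 had ratios above 0 and 26 of them a limma adjusted p under 0.05. Genes lower in the sigU mutant and higher here numbered 2, lovR and sigU itself, where independent lists would share 0.0299. Without the manipulated genes this leaves lovR, against 0.0224. Of 8 general stress regulators 3 were higher, 3 adjusted over the list alone (limma camera adjusted p = 3.15e-05, and adjusted p = 0.0423 with an estimated correlation). They were lovR and the manipulated genes sigU and sigT, without which 1 of 6 was higher and the limma camera adjusted p was 0.0245, or 0.236 with an estimated correlation. Of the 16 lower genes 7 had values on all 3 arrays, 5 share probe sequences with another locus, and 9 genes were lower once a trend with probe G content was removed. On slide 4 all 16 lower and 14 higher genes kept their direction. On replicate 1, whose slide is not known, 11 and 14 did, 11 being all the lower genes with a value there. Called on these same arrays, the genes could hardly do otherwise.

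The other lists had few members called. Of 12 cell cycle regulators, ctrA, the master response regulator gene, fell to -1.02 ± 0.20 in the phyK mutant and had -0.87 ± 0.27, -0.82 ± 0.07 and -0.87 ± 0.30 in the phyR, sigT and sigU mutants (SD, n = 3), without a call in these. The ctrA call in the phyK mutant was lost without replicate 1, at -0.99, and without replicate 2, at -0.94. The ccrM transcript had 0.71 ± 0.31 and 0.81 ± 0.22 in the phyK and phyR mutants and -0.43 ± 0.18 in the sigU mutant (SD, n = 3). By list, 1, 0, 1, 0 and 0 members were called in the phyK, phyR, sigT and sigU mutants and with overexpression, the same numbers adjusted over the list alone. The limma camera adjusted p was 0.648, 0.966, 0.568, 0.0721 and 0.947. Between sigU and sigT mutants 2 members differed (2 adjusted over the list alone), ccrM and pilA, the pilin gene, at -1.16 (SE 0.25), with a list adjusted p of 0.194 from limma camera. Of 5 xylose catabolism genes 0 were called in the 4 mutants. With overexpression 1, CC0823, was higher by 2.83-fold (limma adjusted p = 1.94e-10), 1 adjusted over the list alone. Its upstream probes at bases -195 and -144 had 1.84 and 1.95, and that at base -246 had 0.40. The other members had -0.11 to 0.12. The gene with the next tag after CC0823, which is not on the list, was also called higher with overexpression. What raised either gene was not tested. For this list the limma camera adjusted p was 0.282, 0.412, 0.366 and 0.0582 in the mutants and 0.137 with overexpression. Neither list passed in the contrasts between the phyK, phyR and sigT mutants, where the lowest limma camera adjusted p was 0.108.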

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

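The tests of dye effect and of mixed RNA for the 8 raised genes, of probe G content and of probes called without the array they are read on were chosen only after the result was seen, and the other tests in this part were set beforehand. Sense probes upstream of the start codon, antisense probes and tiles over the replication origin lie outside the gene values above, and each set held probes past the call in the arrays. Upstream sense probes past the call numbered 1546 in the phyK mutant, 1706 in the phyR mutant, 1742 in the sigT mutant, 253 in the sigU mutant and 1316 with sigU overexpression. With overexpression 1243 of these were lower and 73 higher, while in the mutants 625, 628, 638 and 67 were lower and 921, 1078, 1104 and 186 higher. Antisense probes past the call numbered 170, 189, 192, 24 and 272 in the same order, of which 52, 64, 67, 6 and 267 were lower. Origin tiles past the call numbered 13, 14 and 13 in the phyK, phyR and sigT mutants and 12 with overexpression, of which 6, 6, 3 and 12 were lower.

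With sigU overexpression more probes fell than rose in all 4 classes, with 267 of 4231 antisense probes that had a value lower (6.31%), 4.39% of upstream sense probes, 4.46% of origin tiles and 2.71% of coding sense probes (264 lower, 44 higher). Of the 267, 128 had values on all 3 arrays and 61 on 1. Their medians per array, at most -1.15, decide nothing, since they were picked on these arrays. Probes called without an array still had a median of -1.07 or lower on it, which argues against a single array. Fallen antisense probes had a median log2 signal of 10.28, against 7.11 for all antisense and 8.91 for coding sense probes, which argues against dimness. Coding probes matched on signal fell in 1.24% of cases, but they were matched to all antisense probes, not to the fallen ones. A median of 0.09 over the 12 mutant arrays argues against a dye effect. Total G and C content differed by -1.67 points between fallen and other antisense probes, under the 2 points set beforehand as the bound against it, so G content alone was tried after the base percentages had been seen, and coding sense probes with at least 38.3% G fell 15.7 times as often as those with at most 28.3% (7.52% against 0.479%). G content of the probes may contribute to the fall, but in the phyK mutant G-rich probes were less often lower (1.47% against 3.27%) and less often higher (1.1% against 7.5%). Ratios of coding sense probes correlated with percent G at -0.319 with overexpression. In the phyK, phyR, sigT and sigU mutants this correlation was -0.106, -0.148, -0.188 and -0.00491. Why G content would act so with overexpression stays open, and an effect of sigU on RNA outside genes was not tested.

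A set of 8 genes, CC2696 and CC2740 among them, was higher in all 4 mutants, with a median of 2.18 over the mutants, except on sigU mutant replicate 3, where their median was 0.13. Most of the 8 have tags in the range from CC2696 to CC2740, and a change of a region of the genome was not tested. A median of -0.06 for these genes with overexpression, at the same dye orientation, argues against a gene-specific dye effect. On sigU mutant replicate 3 their Cy3 level lay -0.48 from the median of the other 11 mutant arrays. That argues only against wild type RNA on this array unlike the other wild type RNA. The Cy3 levels were 7.42 there and 7.66 to 8.24 on the others. Whether wild type RNA was unusually low in these genes on all mutant arrays was not tested. The Cy5 level on that array lay -2.87 from the median of the others, at 7.52 against 9.79 to 11.13. That is consistent with mutant RNA on this array unlike that on the others, as a hypothesis. Wild type RNA mixed in is argued against as the whole cause. The 8 genes would need a share of 0.969, which leaves sigU at -0.04 where it had -1.42 (-2.95 and -2.76 on the others). The other 61 genes lower in the phyK, phyR and sigT mutants had a median of -0.48 there against -0.25 and -0.58. A smaller share stays open. For its own value sigU would need 0.272, which leaves the 8 genes at 1.71 where they had 0.13. Apart from sigU, 16 genes called lower without this array had a median of -0.50 on it, against -1.15 and -1.16 on the others. They were picked on those others, which favours a weaker value here. A culture difference or a further mutation also stays open and was not tested.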

How the results depend on the processing

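Settings that used all sense probes, start-spanning probes, complete genes, unshared probes or G content, or left out the genes the strains delete or overexpress, were chosen only after the result was seen. Over 22 settings besides left-out arrays, 317 of 364 counts stayed within 1.5 times, and 78 of 81 with an array left out did. Causes were not tested unless stated. Between 88.6% and 98.9% of probes were well above background, and what signal limits beyond the remainder was not tested.

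With the software's processed signals, the sigU mutant had 16 lower and 21 higher genes and overexpression 27 higher. With median centring it had 17 and 20, and 12 genes were lower in both sigT and sigU mutants. Scale normalization gave 26 lower and 23 higher with overexpression. Array weights gave 1 gene between sigT and phyK mutants. The deposited table gave 16 and 19 in the sigU mutant and 27 higher with overexpression.

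All sense probes gave 37 and 33 (lower, higher) in the phyK mutant, 36 and 41 in the phyR mutant, 33 and 39 in the sigT mutant, 1 lower in the sigU mutant and 1 and 1 with overexpression. They gave 52 between sigU and sigT mutants, 27 lower in the phyK, phyR and sigT mutants, 0 in both sigT and sigU mutants, 1 lower in the sigT mutant and higher with overexpression, and 0 lower in the sigU mutant and higher with overexpression. By construction these values include probes outside the transcripts, and 3 of the named values called with coding probes changed sign: sigU in the phyK mutant at 0.02, sigU in the sigU mutant at 0.33 and CC3466 with overexpression at -0.10. Genes lower with overexpression were 4 with start-spanning probes, 7 with complete values and 9 without the G content trend.

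Without the fold minimum, lower and higher genes were 894 and 884 (phyK), 893 and 1002 (phyR), 869 and 1048 (sigT), 681 and 447 (sigU) and 467 and 414 (overexpression). The difference of sigU and sigT mutants was 1024, and the overlaps were 615, 385, 98 and 66 in the order above. List tests past 0.05 were 7, with 4 at an estimated correlation, 13 with fry, which tests the members against 0, and 5 without the genes the strains delete or overexpress. Without these, 1 gene was lower in the sigU mutant and higher with overexpression, by construction.

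With arrays left out, genes lower in the sigU mutant were 5 to 17 (5 without replicate 2, 17 without replicate 3) and those between sigT and phyR mutants 0 to 1 (1 without phyR replicate 3).

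With the replicate number as a block, 78 and 97 genes were lower and higher in the phyK mutant, 19 lower with overexpression and 135 between sigU and sigT mutants, and it moved no count by over 1.5 times. Same-numbered mutant arrays had a median correlation of deviations of 0.2215, and so had arrays on 1 slide.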

Other observations

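Tests of where transcripts begin and of other splits of the arrays were chosen only after the result was seen, and the searches for the promoter element were set beforehand. A sequence known for promoters of this sigma factor family, GGAAC and CGTT 15 to 17 bases apart, was searched in the 400 bases upstream of start codons, in 3491 loci with at least 0.9 of the window covered. It stood upstream of 14 of 57 searched genes among those lower in the phyK, phyR and sigT mutants and of 10 of 3434 other loci. The sequence is GGAACCTTCGCCGCTGCGGGCCGTT at sigU, GGAACCTGGAACCCGCGTGGTCGTT at lovR, GGAACCGTCGAGTTGAGCGGGCGTT at phyR and GGAACCGGGTACGGAAAACCACGTT at nepR, and the last also lies upstream of sigT, 256 bases from its start codon. In these 14 genes the median distance from CGTT to the start codon was 49 bases. The 14, and the tests of presence below, count the element shared by nepR and sigT once for each gene.

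Presence of the element had an odds ratio of 111 for the lowered genes (Fisher's exact test, two-sided, p = 3.01e-20), which is consistent with direct control of part of this set by SigT or a related sigma factor. Of 80 searched genes that rose in the phyK, phyR and sigT mutants 0 had it (odds ratio 0, Fisher's exact test, two-sided, p = 1), so such control of the raised genes through this element finds no evidence here. Genes that also rose with sigU overexpression carried it in 4 of 10 cases against 10 of 47 other lowered genes (odds ratio 2.47, Fisher's exact test, two-sided, p = 0.24), too few to tell. These 4 include sigU, which is overexpressed, and sigT, which both strains lack, and the test was not repeated without them. Of the 10 other loci with the element, 2 had -0.5 or lower in the sigT mutant.

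Transcripts that begin at the element would place the fall after it. In the sigT mutant the median paired difference from probes before the element was -2.14 over all probes after it and -1.90 over probes that begin between element and start codon. It was -1.63 with each element counted once and without probes that share 20 or more bases with a coding probe of a lowered gene. None of these values decides, since the genes were picked for low coding probes and even in the last comparison 9 probes reach into such a probe of their own gene. In lovR probes before the element, at bases -195 and -130, already had -2.47 and -3.11, and where transcripts begin stays open.

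Other splits of the arrays are too few for a share under 0.05, with 10 splits of 6 arrays or 4 sign patterns of 3 arrays. Real counts were 174, 178, 194, 19 and 30 genes called in the phyK, phyR, sigT and sigU mutants and with overexpression, where the highest other pattern gave 1, 1, 1, 0 and 6, and the real pattern was the only 1 of 4 to reach its count. The contrast of sigU and sigT mutants gave 132, the highest other split 0, and 1 of 10 splits reached the real count. The other contrasts gave 0 by limma, with highest other splits of 1, 1 and 0, so 10 of 10 reached it. At an unadjusted p under 0.05 these had 74 of 3747, 256 of 3748 and 142 of 3750 genes, where a share of about 0.05 would do so without any difference.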
